A study of Mus musculus with 6 samples.

How the data were processed

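RNA from 6 cultures of the mouse lung tumour line 393P, 3 with a control vector and 3 with MKK4 shRNA, was labelled with biotin and hybridised to 1-colour Affymetrix arrays, per the labels' protocols. The labels disagree on delivery: the series design describes retroviral infection, and the treatment protocol describes transfection with Lipofectamine of vectors bought from OriGene. The deposited values are intensities on a linear scale, 1 per probe set, never negative and with 1475 to 1633 values at exactly 1 on each array. The method that summarised probes, the background correction and the normalization applied before deposit are not given in the sources used here. The array medians, 92 to 95.76 units, were nearly but not exactly equal, so the values were normalized between arrays as planned for such a case. The number of arrays limits the precision, and the 3 trpnX probe sets of a bacterial control transcript reached at most 26.5 to 39.5 units per array, a level near which an intensity says little.

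A pseudocount of 16 was added to the deposited intensity and log2 was taken; fold changes are on this scale, which understates changes of dim genes. Means and SDs in intensity units are of the values as deposited. The log2 values were quantile-normalized with limma 3.58.1 in R 4.3.3, and the 64 control probe sets were left out of the tests. The platform annotation pairs 34945 probe sets with 1 gene, 932 with several and 9160 with none listed; those without a single gene were tested on their own only. For a gene with several probe sets the one with the highest mean over all 6 arrays was kept, which gave 18193 genes, of which 18031 were found in the reference table by their Entrez number and 18030 had a chromosome (GRCm38.p6, used for names and order only).

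Groups were compared with limma (lmFit, eBayes with a trend in the prior variance) and Benjamini-Hochberg adjustment at 0.05, with group as the single term. The labels' replicate letters entered as a block in an alternative. Map2k4 and the 3' against 5' ratios were also tested by exact two-sided permutation. Named genes were Map2k4, then the 12 largest rises and 12 largest falls among called genes whose groups did not overlap and whose brighter group lay above the median gene, passing over symbols of unnamed clones, then up to 4 called members of each gene list by size, and a fixed set of genes. Genes of that fixed set that are absent from the tables were not analysed here. These rules, the comparisons and the alternatives were set before the data were examined, except the comparison of chromosome medians, chromosome centring and the 3' against 5' ratios of 18S ribosomal RNA, which were chosen after seeing the data.

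The 28 gene lists were written before the data were examined: MKK4, JNK and p38 cascade, AP-1 and immediate early genes, ERK output, PPAR gamma and its targets, epithelial genes, mesenchymal genes, matrix proteases, integrins and matrix receptors, mitosis, G1/S and replication, CDK inhibitors, p53 target genes, apoptosis regulators, interferon response, NF-kappaB targets, TGF-beta, BMP and YAP targets, hypoxia and glycolysis, cholesterol and fatty acid synthesis, unfolded protein and amino acid response, oxidative stress, lung epithelial lineage, growth factors, Notch and Wnt, oxidative phosphorylation, cytosolic ribosomal proteins, and fibroblast, leukocyte and endothelial markers. Some genes stand in more than 1 list. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over the 28 lists, and alternatively with an estimated correlation and with fry, which tests whether the genes of a list move on balance 1 way without comparing them with other genes. None of the 28 lists passed with an estimated correlation.

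Alternatives were the values as deposited, centring on array medians, pseudocounts of 1 and 64, leaving out the dimmer genes, averaging all probe sets of a gene, leaving out probe sets that can match several transcripts, no trend in the prior variance, the replicate block, every probe set on its own, and leaving out each array in turn. The 16 settings given for a gene or list are these, except the test of every probe set, with chromosome centring; 15 where a gene or list drops out with the dimmer genes or a gene has no probe set left without those that can match several transcripts, and the setting as reported is not among them. The test was checked on simulated data with 18193 genes, of which 200 were changed. Of genes changed by 0.5 on the log2 scale 57% were recovered, and of those changed by 1, 83%. Unchanged genes made up 1.41% of calls. With no gene changed the calls were 0, while camera called 1 list that had no shift. The simulated genes were drawn independently, so the check does not cover correlation between genes, estimated at 0.253 for the mitosis list. Its changes were also larger than the median called change in the data, 0.28.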

Results

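Gene expression was measured in 393P, a line of mouse lung tumour cells grown from a primary tumour, carrying either a control vector or a vector expressing a short hairpin RNA (shRNA) against MKK4. MKK4 is the kinase encoded by Map2k4 that activates JNK and p38. Each group had 3 arrays, which the labels call triplicate cultures, so p-values measure the spread between cultures of 1 cell population per group. The 6 arrays had median intensities of 92 to 95.76 units over 45101 probe sets, and correlated with each other at r = 0.991 to 0.996 across genes. The comparison asks which transcripts differ when MKK4 is depleted.

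The targeted transcript was lower in all 3 shRNA cultures. Map2k4 gave 645 ± 51.8 intensity units (SD, n = 3) with the control vector and 274 ± 29.7 (SD, n = 3) with the shRNA on the brighter of its probe sets. This was a 2.31-fold fall, a log2 change of -1.21 with an SE of 0.079 and a limma adjusted p of 0.000127. The other Map2k4 probe set went from 207 ± 5.89 to 90.3 ± 0.741 units (SD, n = 3), a log2 change of -1.08. An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. Map2k4 lies on chromosome 11 of GRCm38.p6.

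The largest rises were in genes of varied function. Bgn, which encodes the matrix proteoglycan biglycan, rose 5.51-fold from 807 ± 20.6 to 4575 ± 147 units (SD, n = 3), and its 3 probe sets gave log2 changes of 2.46, 2.67 and 2.69. Mei4, a gene of meiotic recombination, rose 7.51-fold from 44.1 ± 6.62 units (SD, n = 3). Cers6, a ceramide synthase gene, rose 6.01-fold from 55.2 ± 16.3 units (SD, n = 3). These 2 control levels lie near the trpnX background controls (up to 39.5 units), so the size of the folds is uncertain. Cp, which encodes the copper-binding ferroxidase ceruloplasmin, rose from 29.5 to 268 units, and the kinesin gene Kif21a from 39.3 to 287; both control levels lie no higher than the trpnX background controls reach (39.5 units), so no fold is given. Vcam1, an adhesion molecule of the immunoglobulin family, rose 3.85-fold from 108 ± 8.50 to 472 ± 75.8 units (SD, n = 3). Bbx (2.40), Arhgap6 (2.22), Arsb (2.12), Aldh1l2 (1.99), Prkar2b (1.75) and Ugt2b34 (1.71) also rose, the values being log2 changes. The size of several rises rests on part of the probe sets: another Arsb probe set of similar brightness gave 0.07, the other Bbx probe sets -0.03 to 1.62, another Kif21a probe set of similar brightness 0.88, the Cp probe set above background in both groups 0.62, and another Vcam1 probe set of similar brightness 0.90.

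The largest falls were smaller. Rtn2, a reticulon gene, fell 2.73-fold from 214 ± 3.62 to 69.1 ± 12.9 units (SD, n = 3), and Ppbp, which encodes a CXC chemokine precursor, fell 2.58-fold from 1693 ± 80.2 to 655 ± 83.0 units (SD, n = 3). Acsl6, a long-chain acyl-CoA synthetase gene, and Tspan1, a tetraspanin gene, fell 2.23-fold and 2.16-fold. Log2 changes of the receptor tyrosine kinase gene Ret (-0.94), Nnat (-0.93), Rasgrp3 (-0.89), Gcnt3 (-0.83), Nfe2l3 (-0.82), Tmprss11e (-0.82) and the intermediate filament gene Nes (-0.81) completed the 12 largest falls with Map2k4. Another Nes probe set gave 0.07, and the mean of the Nes probe sets did not pass the test (adjusted p = 0.0513, the highest of 16 settings). The dimmer Tspan1 probe set, used when those that can match several transcripts are left out, gave -0.37 and did not pass (0.0592, the highest of 16 settings). The size of 2 other falls also depended on the setting: the smallest log2 changes were -0.64 for Acsl6 and -0.47 for Rasgrp3, both still called.

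Across 18193 genes, limma with Benjamini-Hochberg adjustment called 2139 changed, 1158 higher and 981 lower with the shRNA, and 4384 passed an unadjusted p of 0.05. Most called changes were small: the median size was 0.28 on the log2 scale, and 1897 of the 2139 were under 1.5-fold. At least 2-fold changes were 68, of which 61 were rises and 7 falls. The groups did not overlap in 5185 genes, or 28.5%, against 10% by chance. Members of the 28 gene lists were called more often than genes at large, 235 of 1004 against 2139 of 18193. So were brighter genes: without the dimmer genes, 2630 of 9097 were called. A list's count of calls is to be read beside these shares. The count of changed genes was 1351 without control replicate 2, 1324 without control replicate 3, 1159 without shRNA replicate 2 and 1249 without shRNA replicate 3, each fitted on 5 arrays. It was 1127 without a trend in the prior variance and 1206 with the replicate block. As deposited, 971 were higher and 565 lower, and with centred medians 877 and 561. The 2-fold count was 113 (91 rises, 22 falls) with a pseudocount of 1 and 38 (34 rises, 4 falls) with 64. It was 29 (26 rises, 3 falls) without the dimmer genes and 140 (130 rises, 10 falls) over every probe set.

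**Figure D1:**
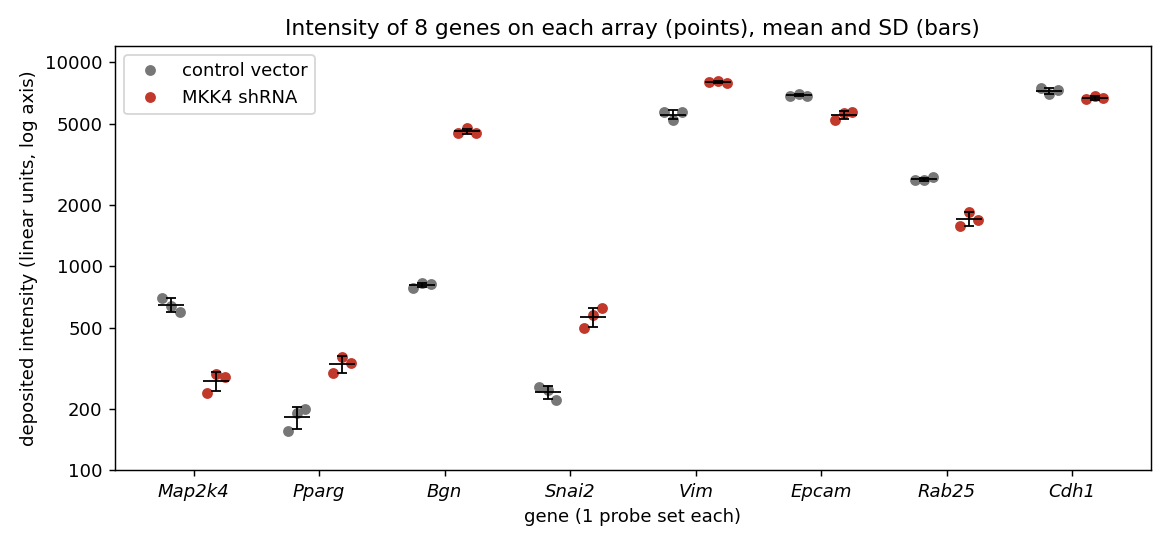
Deposited intensity, in linear units on a log axis, of Map2k4, Pparg, Bgn, Snai2, Vim, Epcam, Rab25 and Cdh1 on each array, with 3 points per group and bars for the mean and SD. Map2k4 lies near 645 units with the control vector and near 274 with the shRNA, while Bgn goes from near 807 to near 4575.

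Some genes of epithelial identity were lower and some mesenchymal genes higher in the shRNA cultures. Of 41 measured epithelial genes 15 fell and 2 rose, and 24 did not pass the test. Rab25, a small GTPase of apical recycling, fell from 2664 ± 49.1 to 1705 ± 132 units (log2 -0.65), and the polarity genes Crb3 (-0.37) and Pard6b (-0.34) and the adhesion gene Epcam (-0.35) fell too. Cdh1, which encodes E-cadherin, went from 7236 ± 264 to 6684 ± 131 units (SD, n = 3), a log2 change of -0.14 with adjusted p = 0.0182. Of 39 measured mesenchymal genes 9 rose and 1, the lysyl oxidase relative Loxl1, fell. Beside Bgn, Snai2, a transcriptional repressor of E-cadherin, rose 2.21-fold from 242 ± 17.9 to 564 ± 62.6 units, and Vim, the gene of vimentin, rose 1.42-fold from 5531 ± 274 to 8008 ± 83.3 units (SD, n = 3), with log2 changes of 0.76 and 0.69 on its other probe sets. Tnc, the gene of tenascin C, rose by 0.75 on the log2 scale.

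The counts adjusted over the list alone were 18 epithelial genes lower and 2 higher, and 10 mesenchymal genes higher and 1 lower. The limma camera test gave adjusted p = 4.65e-05 for the epithelial list, lower, and 0.0343 for the mesenchymal list, higher, but adjusted p = 0.35 with an estimated correlation for each. Snai1 gave a log2 change of -0.20 (adjusted p = 0.383) and Zeb1 -0.04 (0.891). Zeb2 gave 0.09 on its brightest probe set (0.661), but 1.65 on a dimmer one (42.1 to 167 units) and a rise from within background to 43.6 units on another, and the mean of its probe sets passed the test at 0.63. Over 16 settings the adjusted p of the mesenchymal list ran from 4.64e-06 to 0.084, and it passed in 12, not without shRNA replicate 1 (0.0828) or shRNA replicate 3 (0.084). Cdh1 passed in 8 of 16 settings, with adjusted p up to 0.15, and Tnc in 8 of 15, up to 0.335.

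Within the kinase cascade that MKK4 belongs to, Map2k4 and 4 other genes fell and 3 rose among 40 measured. Map2k6, which encodes another activator of p38, rose by 0.66 on the log2 scale, and Mapk13, a p38 isoform gene, fell 1.55-fold from 1746 ± 37.5 to 1129 ± 77.2 units (SD, n = 3). Mapk8ip1, which encodes a JNK scaffold, changed by -0.59 on its kept probe set, but by 0.09 without probe sets that can match several transcripts. The JNK genes Mapk8 (0.22, adjusted p = 0.131) and Mapk9 (0.11, 0.378) and the p38 gene Mapk14 (-0.05, 0.566) did not pass the test. Adjusted over the list alone, 3 rose and 8 fell, and limma camera gave adjusted p = 0.237. Over 16 settings the list's value ran from 0.0205 to 0.385, and it passed in 1, after chromosome centring (0.0205, with 2 higher and 7 lower). With an estimated correlation after centring, camera gave adjusted p = 0.202. The list passed by fry, which makes no comparison with other genes, as lower (adjusted p = 0.00307). Map2k4, the target of the shRNA, is itself a member and adds to the list's fall. Mapk8 passed in 2 of 16 settings, without the dimmer genes (0.045) and without shRNA replicate 1 (0.039), over a range up to 0.737, and another of its probe sets rose by 0.34.

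Immediate early genes and AP-1 genes gave more falls than rises. Of 31 measured, 10 fell, 3 rose and 18 did not pass the test: Dusp1, a phosphatase gene of MAP kinases, fell from 3207 ± 47.6 to 2158 ± 97.4 units (log2 -0.57), Rhob fell by 0.57, Ier3 by 0.36 and Jun, an AP-1 subunit gene and the namesake substrate of JNK, by 0.39, from 511 ± 20.4 to 391 ± 9.53 units (SD, n = 3). Of 25 genes of ERK output 8 fell, among them Dusp7 (-0.30), Lif (-0.27) and Egr1 (-0.26), and 2 rose. Among AP-1 genes 11 were lower and 5 higher adjusted over the list alone, and among ERK genes 10 lower and 4 higher. Limma camera gave adjusted p = 0.047 for the AP-1 list, and adjusted p = 0.35 with an estimated correlation, and 0.1 for the ERK list. Over 16 settings the AP-1 value ran from 0.0131 to 0.113 and passed in 6; leaving out control replicate 1 (0.0781), control replicate 2 (0.0561) or shRNA replicate 1 (0.0703), 2 (0.072) or 3 (0.0524) ended the call. The ERK list passed in 1 of 16, without control replicate 3 (0.0489, range 0.0489 to 0.267), Egr1 in 10 of 16 and Dusp7 in 14 of 15. Both the AP-1 and the ERK list passed by fry as lower (adjusted p = 0.00307 each).

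Pparg, which encodes a nuclear receptor of fat cell differentiation, rose 1.73-fold from 182 ± 22.7 to 331 ± 31.4 units (SD, n = 3), a log2 change of 0.79 with an SE of 0.099 and a limma adjusted p of 0.00207. Cebpd, a transcription factor gene of the same programme, rose by 1.19 on the log2 scale from 69.9 units, while a dimmer probe set with a control level within background (32.4 units) did not pass. The fatty acid oxidation gene Acadvl changed by 0.26 and Acadm by -0.16. Of 40 measured PPAR gamma genes 3 rose and 2 fell, also adjusted over the list alone, and limma camera gave adjusted p = 0.367. This list passed by fry as higher (adjusted p = 0.0304). The Acadm call passed in 6 of 16 settings, with adjusted p up to 0.181, and Acadvl, on chromosome 11, in 15 of 16, not after chromosome centring (0.14, adjusted p = 0.113, the highest of 16).

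Genes of the unfolded protein and amino acid responses moved in both directions. Of 37 measured, 16 rose, 7 fell and 14 did not pass the test. Vldlr, a lipoprotein receptor gene, rose 2.33-fold from 264 ± 6.35 to 647 ± 34.9 units, Ern1, the gene of the stress sensor IRE1, 1.97-fold, Ddit3, the gene of the stress transcription factor CHOP, 1.76-fold from 598 ± 66.7 to 1071 ± 37.8 units, and Ppp1r15a, which encodes a phosphatase subunit acting on eIF2, 1.65-fold (SD, n = 3). The 7 that fell, named after their values were seen, were the chaperones and folding enzymes Pdia3 (-0.44), Pdia6 (-0.34), Calr (-0.33), Pdia4 (-0.30) and Hsp90b1 (-0.25), the sensor kinase Eif2ak3 (-0.29) and the transcription factor Xbp1 (-0.16). The test called 17 higher and 8 lower adjusted over the list alone. Limma camera gave adjusted p = 0.00438, higher, and adjusted p = 0.35 with an estimated correlation. The other Vldlr probe sets gave 0.25 to 1.34 and the other Ern1 probe sets above background -0.14 to 0.20, and the mean of all Ern1 probe sets did not pass the test (adjusted p = 0.115, the highest of 16 settings).

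In lipid synthesis, 11 of 36 measured genes rose and 2 fell. Acaca, the gene of acetyl-CoA carboxylase, rose from 924 ± 23.8 to 1179 ± 16.8 units (log2 0.34) and Scd1, a fatty acid desaturase gene, from 3178 ± 102 to 3979 ± 175 (0.31). The sterol reductase genes Dhcr7 (-0.57) and Tm7sf2 (-0.47) were the 2 that fell. For this list 13 were higher and 5 lower adjusted over the list alone; limma camera gave adjusted p = 0.0343, higher, and adjusted p = 0.467 with an estimated correlation. Over 16 settings the value ran from 0.00907 to 0.2 and passed in 8, not without control replicate 1 (0.0781) or 2 (0.0561) or shRNA replicate 2 (0.113) or 3 (0.0855). Acaca did not pass with its probe sets averaged (0.128, the highest of 16). By fry the lipid synthesis list did not pass (adjusted p = 0.101).

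Some mitotic genes were lower in the shRNA cultures. Of 44 measured, 9 fell, 1 rose and 34 did not pass the test: the checkpoint kinase gene Bub1 fell from 1843 ± 127 to 1361 ± 145 units (log2 -0.45), the proliferation marker Mki67 from 1141 ± 80.4 to 863 ± 109 (-0.42), and the spindle genes Nusap1 and Kif11 by 0.39 and 0.36. Of 45 genes of G1/S and replication 4 fell, among them Pcna (-0.19) and Ccnd3 (-0.20), and 1, Mcm3 (0.19), rose. Of the mitotic genes 10 were lower and 2 higher adjusted over the list alone, and of the G1/S genes 4 lower and 1 higher. Limma camera gave adjusted p = 0.00169 for mitosis, lower, and adjusted p = 0.467 with an estimated correlation, and 0.3 for G1/S. By fry the mitosis list did not pass (adjusted p = 0.0742). Pcna passed in 7, Ccnd3 in 6, Mcm3 in 11 and Kif11 in 15 of 16 settings, with adjusted p up to 0.886, 0.883, 0.243 and 0.0599. Pcna, on chromosome 2, gave -0.014 after chromosome centring (adjusted p = 0.886, the highest of 16).

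Regulators of arrest and death changed in both directions. Among 16 CDK inhibitors and cell cycle brakes, the INK4 locus genes Cdkn2a (0.40) and Cdkn2b (0.19) and Tob1 (0.24) rose and Cdkn1c (-0.46) fell. Of 33 p53 target genes 5 rose, such as the stress gene Ddit4 (0.35), and 4 fell, such as the BH3-only gene Pmaip1 (-0.57), the repair gene Xpc (-0.38) and the junction gene Perp (-0.29). Of 33 apoptosis regulators 6 fell, such as Pmaip1, the BH3-only gene Bcl2l11 (-0.40) and the caspase gene Casp6 (-0.23), and 1, Bcl2l2 (0.24), rose. Adjusted over the list alone, the higher and lower counts were 3 and 1, 5 and 5, and 1 and 6. The limma camera adjusted p was 0.756, 0.829 and 0.19 in that order, and none of these lists passed in any of 16 settings. Apoptosis regulators passed by fry as lower (adjusted p = 0.0191), while the CDK inhibitor and p53 lists did not (0.474 and 0.421). Bcl2l2 and Tob1 changed sign when the probe sets of a gene were averaged, to -0.01 and -0.17; Cdkn1c passed in 9 of 15 settings, and Pmaip1 in 12, Casp6 in 10, Cdkn2b in 14 and Xpc in 15 of 16.

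Matrix proteases and adhesion receptors gave more falls than rises. Of 43 protease and inhibitor genes 7 fell, among them the plasminogen activator gene Plat, from 739 ± 39.0 to 494 ± 39.5 units (log2 -0.59), Mmp16, from 39.5 to 20.4 units, and Serpinb2, from 43.6 to 25.1 units, and 2 rose, among them Adamts1 (0.54). The gelatinase genes Mmp2 (0.04, adjusted p = 0.928) and Mmp9 (-0.05, 0.764) did not pass the test. Of 36 integrin, laminin and matrix receptor genes 5 fell, among them the collagen receptor gene Ddr1 (-0.34) and the dystroglycan gene Dag1 (-0.21), and 2, Itgb5 (0.37) and Cd47 (0.35), rose. For proteases 9 were lower and 2 higher adjusted over the list alone, and for receptors 5 lower and 2 higher. The limma camera adjusted p was 0.181 and 0.159. Proteases passed by fry as lower (adjusted p = 0.019), while the receptor list did not (0.0621). Mmp16 passed in 7 and Serpinb2 in 13 of 15 settings, with adjusted p up to 0.715 and 0.052, and their shRNA levels lie within background, so no fold is given. Cd47 passed in 15, Adamts1 in 14 and Dag1 in 12 of 16, up to 0.31, 0.0548 and 0.0848, and other bright Cd47 probe sets gave 0.17 and 0.12. Plat passed in each of 16 settings, but its smallest log2 change among them was -0.28.

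NF-kappaB targets, chemokines and cytokines gave 7 rises and 3 falls among 46 measured. Beside Vcam1, Csf1, a macrophage growth factor gene, rose 2.19-fold from 617 ± 34.1 to 1389 ± 27.0 units (SD, n = 3) on its brightest probe set but gave 0.07 on another bright one (549 to 584 units), the inhibitor gene Nfkbie 2.24-fold and the chemokine gene Cxcl3 1.88-fold. Of 43 interferon response genes, Ifih1 (0.50), Ifi35 (0.45) and Parp14, from 14.6 to 46.3 units, a control level within background that gives no firm fold, rose and 0 fell in limma, with 4 lower at an unadjusted p of 0.05. Among 41 TGF-beta, BMP and YAP targets 8 rose, such as Id3 (0.56) and Bmp4 (0.29), and 3 fell, such as Id2 (-0.73) and the receptor gene Tgfbr1 (-0.35). Adjusted over the list alone, the higher and lower counts were 12 and 3, 3 and 0, and 8 and 5. The limma camera adjusted p was 0.08, 0.427 and 0.92; for the TGF-beta list the test pointed up while the median (-0.03) and mean (-0.02) lay below 0. The NF-kappaB value ran from 0.00983 to 0.296 over 16 settings and passed in 4, among them without control replicate 3 (0.0489), and Bmp4 and Ifih1 each passed in 9, of 16 and of 15. NF-kappaB targets passed by fry as higher (adjusted p = 0.00307), while the interferon (0.0882) and TGF-beta (0.931) lists did not. Bmp4, on chromosome 14, gave 0.16 after chromosome centring (adjusted p = 0.194, the highest of 16). Id2 gave -0.17 without probe sets that can match several transcripts (adjusted p = 0.393) and Tgfbr1 -0.17 with probe sets averaged (0.0934), each the highest of 16 settings; Id3 passed in 12 of 16 and Parp14 in 12 of 15.

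**Figure D2:**
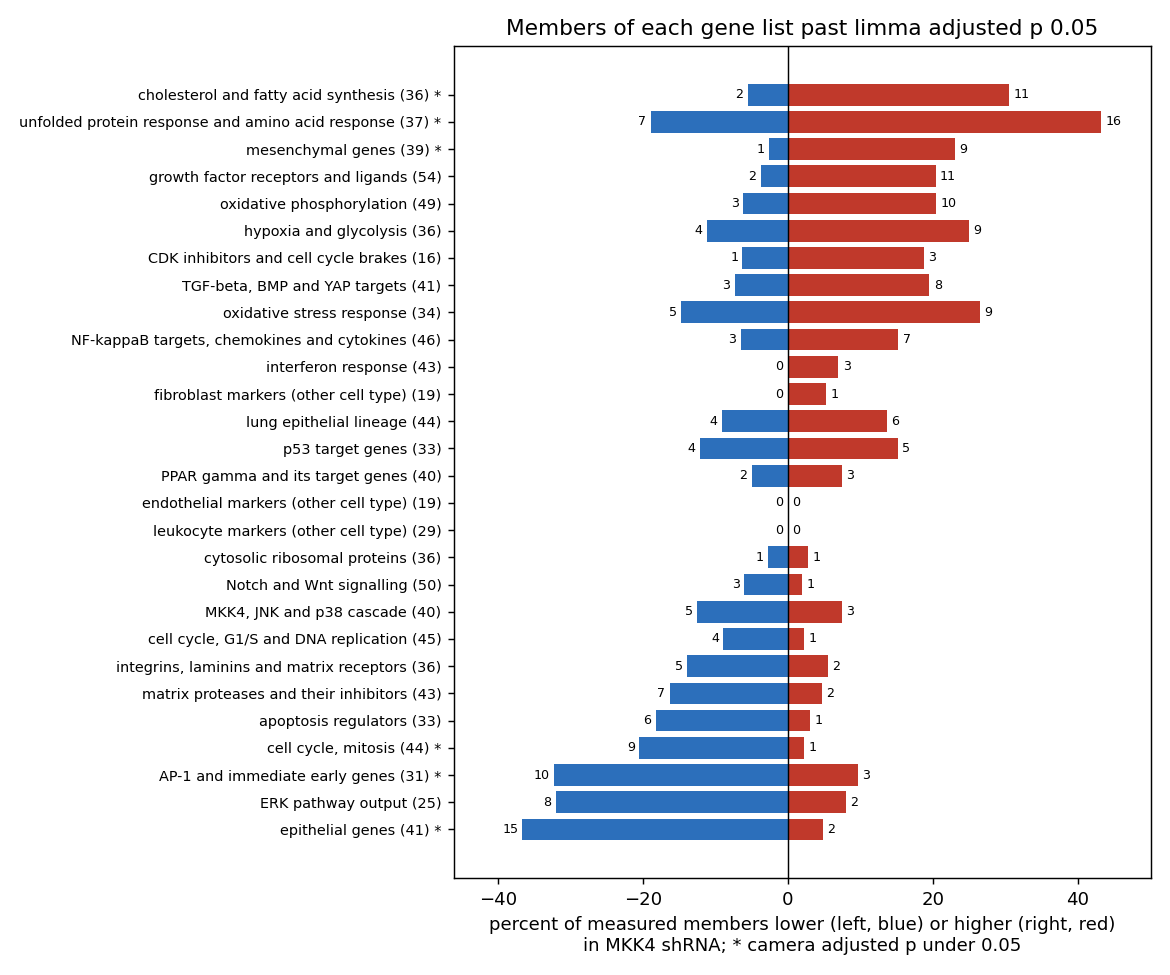
Percent of the measured members of each of 28 gene lists (number measured in brackets) that passed limma's adjusted p of 0.05 as lower (blue, left) or higher (red, right) with the shRNA, with the count at each bar and a star for a camera adjusted p under 0.05 at the preset correlation. Of 41 epithelial genes 15 were lower and 2 higher, and of 37 unfolded protein and amino acid response genes 16 were higher and 7 lower.

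Genes of the same chromosome shifted together, a comparison chosen after seeing the data. Over 9066 genes brighter than the median gene, with chromosomes from GRCm38.p6, the median log2 change was -0.10 on chromosome 2, 0.10 on chromosome 11, 0.10 on chromosome 13 and 0.11 on chromosome 15, and -0.06 on chromosome 19. On chromosome 2, 216 of 761 genes were called lower and 14 higher, while on chromosome 11 the test called 212 of 760 higher and 21 lower. Chromosome 15 had 111 of 362 higher and 10 lower, and chromosome 13 had 98 of 338 higher and 7 lower. These 5 are the chromosomes with a median over 0.05 in size; chromosome 17 (-0.0492, 62 of 456 lower and 15 higher) and chromosome 6 (-0.0455, 55 of 429 lower and 23 higher) lay just under that bound. The 3 shRNA arrays lay outside the range of the controls on each of the 5 and on 9 other chromosomes, 14 of 20. By chance 10% would do so, but the chromosomes share the same 6 arrays and are not independent trials. On chromosome 8 the ranges barely part, with the highest shRNA array at -0.018564 and the lowest control at -0.0185573. Whole-chromosome medians leave out regional shifts: among 10 parts per chromosome, equal in genes, parts 3 to 6 of chromosome 14 had medians of 0.09 to 0.14 and parts 8 to 10 medians of -0.12 to -0.11, which cancel to 0.03, and parts 1 to 3 of chromosome 4 had -0.12 to -0.08. Single end parts of chromosomes 12 (-0.15) and 17 (-0.14) were as low. Map2k4 fell against its chromosome, by 1.34 on the log2 scale once each such part was centred. That centring left 1641 genes changed, of which 1335 were among those called before. It ended the call of the lipid synthesis list (camera adjusted p = 0.2, the highest over 16 settings). It gave calls for the MKK4 cascade (0.0205), hypoxia (0.0431) and oxidative stress (0.0431) lists, so that 8 lists passed in place of 6. With an estimated correlation after centring, camera gave adjusted p = 0.202, 0.202 and 0.355 for these lists, and 0 lists passed. The cascade list holds Map2k4, the target of the shRNA. Chromosome Y, left out above because it holds 4 such genes, had a median of 0.56 with 3 of the 4 higher, and its shRNA arrays lay at 0.47 to 0.61 against -0.03 to 0.04 in the controls.

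**Figure D3:**
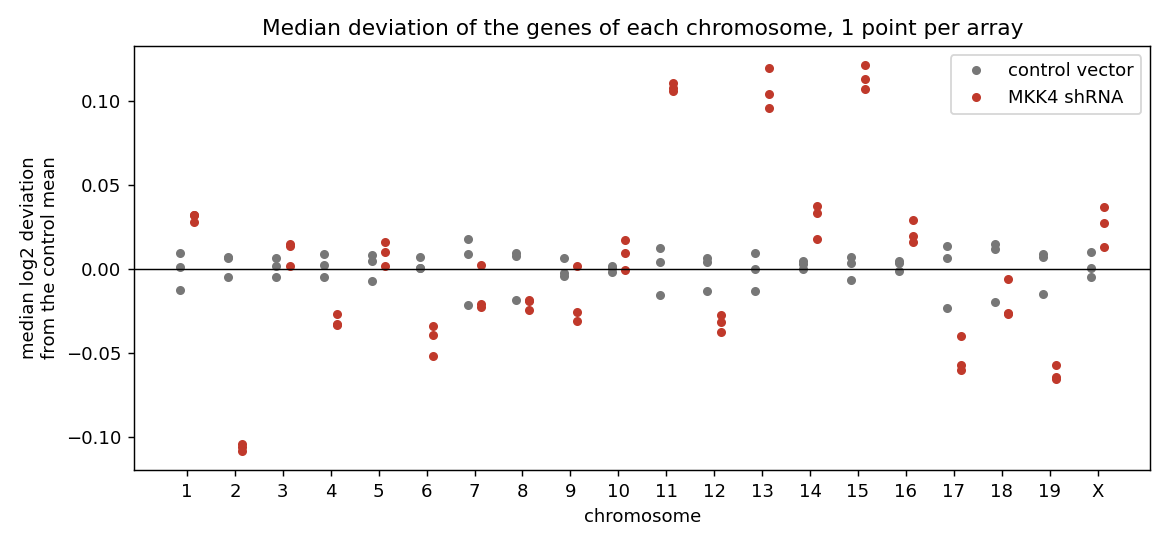
Median log2 deviation from the control mean (vertical axis) of the genes of each chromosome (horizontal axis), 1 point per array, for genes brighter than the median gene. The 3 shRNA points lie between -0.11 and -0.10 on chromosome 2 and between 0.10 and 0.12 on chromosomes 11, 13 and 15.

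Markers of other cell types and of RNA quality were set beside these groups. Among 19 fibroblast markers Fbln2 (0.18) rose and 0 fell in limma, with 3 higher and 0 lower at an unadjusted p of 0.05, and the collagen genes Col1a1 (79.4 to 68.3 units), Col1a2 (205 to 188) and Col3a1 (57.2 to 62.7) did not pass the test. Of 29 leukocyte and 19 endothelial markers limma called 0, with 1 higher and 1 lower leukocyte marker and 0 endothelial markers at an unadjusted p of 0.05. Adjusted over the list alone, 0 of any of the 3 lists passed, and the camera adjusted p was 0.996, 0.811 and 0.912. For fibroblast markers the median (-0.07) and mean lay below 0 while camera pointed up. The difference between the 3' and 5' control probe sets of Gapdh, a measure of RNA quality, changed by -0.0083 on the log2 scale between groups, with an exact two-sided permutation p of 0.6. In a comparison chosen after seeing the data, the 3' probe set of 18S ribosomal RNA was lower with the shRNA (4265 ± 225 to 3236 ± 549 units, SD, n = 3, log2 -0.43, limma adjusted p = 0.0473), while its 5' probe set gave -0.05; the difference between them changed by -0.38 between groups, with an exact two-sided permutation p of 0.1, the smallest possible.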

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

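The test of probe sets without a single gene was planned, and no test in this part was chosen after the result was seen. Outside the tested genes, 219 probe sets that the annotation pairs with several genes or none passed limma's adjusted p of 0.05, 113 of them higher with the shRNA and 106 lower, of which 87 are paired with several genes and 132 with none listed. The 113 are given because they lie outside the comparison of genes and stood above the control arrays. The largest rise among them was 2.19 on the log2 scale, from 73.5 to 396 intensity units.

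The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In each case the real split was the 1 with the largest result: 2139 changed genes against 0 in the highest other split, 68 genes changed 2-fold against 0, 235 changed list members against 0, and 6 shifted lists against 3. Each other split mixes both groups, so a difference between the groups widens its spread and lowers its calls. The counts of 0 are therefore no measure of what chance alone would call. Even so, camera called 1 to 3 lists in several of these mixed splits.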

How the results depend on the processing

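Chromosome centring and the 18S ratios were chosen after seeing the data, and the other alternatives were planned. Map2k4 stayed past the test in every setting, at -1.34 to -1.09 on the log2 scale. Changed genes were 1127 without a trend in the prior variance, 1206 with the replicate block and 1159 to 1662 when 1 array was left out. As deposited they were 1536 (63.2% higher, against 54.1%) and with centred medians 1438 (61% higher). Genes changed at least 2-fold were 113 and 38 with pseudocounts of 1 and 64, 29 without the dimmer genes, 140 over every probe set and 67 to 74 with 1 array left out. Shifted lists were 3 without the trend, 0 with an estimated correlation, also 0 with it after chromosome centring, 14 by fry and 3 to 11 with 1 array left out, 11 without control replicate 3 and 3 without shRNA replicate 3. Changed list members were 152 with the block and 143 to 186 with 1 array left out (155 without control replicate 3, 143 without shRNA replicate 2 or 3). The fits without an array have fewer samples, the dimmer-gene filter tests fewer genes, and a smaller pseudocount enlarges changes of dim genes by construction; otherwise the cause was not tested. In RNA quality, Actb middle against 5' moved to 0.0143, and 18S ribosomal RNA to -0.381 (3' against 5') and -0.267 (middle against 5'), against -0.00835 for Gapdh. The correlations of same-numbered arrays, -0.0842, -0.0257 and -0.321, show no pairing by number, and no array correlated best with its own number. Control replicate 3 with shRNA replicate 1 gave 0.316 and control replicate 2 with shRNA replicate 3 gave 0.248. A pairing in another order is therefore not excluded.

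Among named genes, 4 results reversed: Tob1 (-0.17) and Bcl2l2 (-0.0125) with the mean of all probe sets, and Mapk8ip1 (0.0884) and Atp5g1 (-0.19) without probe sets that can match several transcripts; the cause was not tested, but the Atp5g1 value comes from a probe set within background in both groups (15.5 and 11.6 units), where no sign can be read. In 216 other cases a named gene lost its call, in 3 it gained 1, and in 1708 direction and call stayed as they were. Lists gained the call in 15 cases, lost it in 22 and kept it or stayed without it in 408. These list counts cover the 16 settings, and leave out the estimated correlation (0 lists called) and fry (14 called). Signal near the level of the trpnX controls, at most 39.5 units, limits what dim genes can show.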

Other observations

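Of the tests of explanations in this part, those of 1 array, chance placement, copy number, chromosome centring, fibroblasts, RNA quality and single probe sets were chosen after the result was seen. The metallothionein gene Mt2 rose 2.57-fold from 1332 ± 235 to 3462 ± 324 units and Mt1, another metal-binding protein gene, 1.75-fold (SD, n = 3), within an oxidative stress list of 34 genes with 9 higher, such as the quinone reductase gene Nqo1 (log2 0.54), and 5 lower, such as the efflux pump gene Abcc4 (-0.34). Of 54 growth factor and receptor genes 11 rose and 2 fell. Vegfc, a lymphatic growth factor gene, rose from 33.7 to 135 units, a control level within background (trpnX up to 39.5) that gives no firm fold, the IGF-binding protein genes Igfbp7 and Igfbp3 2.96-fold and 2.21-fold, and the KIT ligand gene Kitl 2.02-fold. Other probe sets gave -0.03 for Igfbp7 (168 to 166 units) and 0.06 for Kitl (204 to 216), and over the settings their lowest log2 changes were 0.67 and 0.53. Among 36 hypoxia and glycolysis genes 9 rose, such as Ero1a (0.42), and 4 fell, such as Pfkfb4 (-0.55) and the collagen hydroxylase gene P4ha2 (-0.54). The higher and lower counts adjusted over the list alone were 10 and 6, 12 and 2, and 11 and 4. The limma camera adjusted p was 0.159, 0.28 and 0.118. The growth factor list had a median of -0.002 but a mean of 0.09. Without control replicate 3 the oxidative stress and hypoxia lists passed (0.0489 each, ranges 0.0431 to 0.27 and 0.0396 to 0.302), and Nqo1 passed in 6 of 15 settings. Without probe sets that can match several transcripts Mt1 did not pass (adjusted p = 0.626, the highest of 16 settings), on a probe set near background (39.6 to 45.4 units). Growth factors passed by fry as higher (adjusted p = 0.0165), while the oxidative stress (0.0699) and hypoxia (0.0653) lists did not.

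Lineage markers of the lung gave calls in both directions: of 44, the surface glycoprotein gene Cd24a rose 2.99-fold from 1126 ± 19.7 to 3420 ± 109 units (SD, n = 3), Sox9, a transcription factor gene of distal lung progenitors, by 0.72 on the log2 scale and the mucin gene Muc5ac by 0.53 among 6 that rose, while Id2 (-0.73) was among 4 that fell. Of 49 oxidative phosphorylation genes 10 rose, such as the complex I genes Ndufs4 (0.30) and Ndufb9 (0.25) and Uqcrfs1 (0.23), and 3 fell. Rpl14 rose 2.90-fold on its 1 probe set and Rps6 (-0.20) fell among 36 cytosolic ribosomal protein genes. Of 50 Notch and Wnt genes Lgr4 (-0.27), Tcf7l2 (-0.26) and Znrf3 (-0.19) fell and Fzd1 (0.21) rose. For these lists the counts adjusted over the list alone were, higher and lower, 6 and 5, 11 and 3, 1 and 0, and 0 and 3. The limma camera adjusted p was 0.996, 0.0888, 0.845 and 0.237; for the lineage list camera pointed down and the median was -0.009, but the mean was 0.03. Oxidative phosphorylation passed as deposited (0.0118), with centred medians (0.0259) and without control replicate 2 (0.03) or 3 (0.0469), over a range of 0.0118 to 0.418. After chromosome centring its rises were 5 in place of 10, and Ndufs4 (0.13, adjusted p = 0.0636), Ndufb9 (0.095, 0.0963) and Uqcrfs1 (0.093, 0.126), on chromosomes 13, 15 and 13, no longer passed, though they did in at least 14 of 16 settings (up to 0.109, 0.0963 and 0.126). Id2 passed in 15 of 16 settings and Muc5ac in 13 of 15. Rps6 passed in 2, Fzd1 in 4, Lgr4 in 6 and Tcf7l2 and Znrf3 in 7 of 16 settings. Ribosomal protein genes passed by fry as higher (adjusted p = 0.033) and the Notch and Wnt list as lower (0.0475). The fry adjusted p was 0.05, higher, for the lineage list and 0.101 for oxidative phosphorylation.

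Genes of chromosomes 2, 11, 13, 15 and 19 shifted together with the shRNA, as did those of parts of chromosomes 4 and 14 and 3 of 4 bright genes of chromosome Y, which the tests leave out for its few genes. A single array does not account for it, since the 3 shRNA arrays lay outside the controls on 100% of the 5 chromosomes, nor does quantile normalization, since the SD of the chromosome medians was 0.0544 without it and 0.0541 with it. A brightness bias is argued against by r = 0.939 across chromosomes between the brighter and dimmer genes, and chance placement by an SD of 0.0683 among the medians of 10 parts per chromosome against at most 0.0309 in 1000 shuffles. A hypothesis is that the 2 cell populations may differ in chromosome copy number: on 100% of these 5 chromosomes both quartiles of the genes moved with the median, as a dose change of most genes would give. These chromosomes were picked for a shifted median, so the quartiles largely restate the shift and decide nothing about its cause. The shifts were also uneven: the medians of the parts of chromosome 11 ran from -0.02 to 0.18. No DNA data were analysed here and each group is 1 population, so a difference that arose during cell selection and an effect of MKK4 depletion itself both stay open.

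For the lower epithelial genes, the chromosome shifts are argued against as the whole cause: after chromosome centring the list's median stayed at -0.12 and its camera adjusted p was 5.29e-08 (over 16 settings up to 0.000472), though adjusted p = 0.35 with an estimated correlation before centring and 0.0579 after it. For the higher mesenchymal genes the chromosome shifts stay open as a part of the cause, since the test decides little. Centring left 57.8% of the median (0.07 before, 0.04 after), but the median before centring is the value of 1 dim gene, Col3a1. Called members were 8 higher and 1 lower after centring, in place of 9 and 1. The camera adjusted p after it was 0.0226 (4.64e-06 to 0.084 over 16 settings). With an estimated correlation camera gave adjusted p = 0.35 before centring and 0.202 after it. Fibroblasts in the cultures are argued against for 7 of the 9 mesenchymal rises (median of the 9, 0.49), but not for Axl, Sparc or the lower epithelial genes: the fibroblast collagen genes above background, Col1a1 (79.4 to 68.3 units), Col1a2 (205 to 188) and Col3a1 (57.2 to 62.7), changed by a mean of -0.0791 on the log2 scale, with a 95% interval of -0.35 to 0.19, which decides nothing against the whole list's median of 0.07, a bound tried earlier that is Col3a1's own value. RNA quality stays open, since its measures differ. The 3' to 5' difference of the Gapdh and Actb mRNAs changed by at most 0.00835 between groups, with no sign of a difference in these mRNAs. That of 18S ribosomal RNA, which is not an mRNA, changed by -0.38. This came from a lower 3' probe set (log2 -0.43, against -0.05 for the 5' probe set). The loss of MKK4 is a candidate explanation that stays open as a hypothesis, since with 1 shRNA and 1 population per group it is not separated from other differences between the populations.

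Rises of at least 2-fold, 61, outnumbered falls, 7. The pseudocount is argued against, since rises stayed at least 4.14 times the falls with pseudocounts of 1 and 64, and so are the chromosome shifts, with a ratio of 9 after centring. Signal of single probe sets cannot be told apart from transcript changes for the rest: of 16 other bright probe sets of 12 of these genes, 75% rose, between the bounds of the test, and the other genes have no such probe set. A real excess of strong rises may remain, as a hypothesis.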
